A study of Homo sapiens with 4 samples.

How the data were processed

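The series holds 4 RNA-seq libraries of U87, an established human glioblastoma cell line, with 1 library in each of 4 groups. Per the labels' protocols, cells grew in serum-containing medium, hypoxia was 1% O2, RNA was taken with Trizol, and libraries were made with an NEBNext Ultra RNA kit. The groups were wild-type (WT) cells in normoxia, WT cells in hypoxia, cells with a scrambled shRNA (shScr) in hypoxia, and cells with an shRNA against ALKBH5 (shALKBH5) in hypoxia.

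The authors deposited FPKM values (fragments per kilobase of gene, scaled to library size) in 2 gene tables, per the file headers. The first holds the 2 WT libraries and the second the 2 shRNA libraries. The tables were normalised separately, so changes were computed within a table, and any level set across the tables is described as such. The submitters' processing notes name hg19. The coordinates in the shRNA table equalled the gene starts and ends of GENCODE release 29, a GRCh38 annotation, in 58676 of 58735 rows, and are given here as GRCh38. The aligner, the counting tool and the use of strand are not given in the sources used here.

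The WT table had 18964 rows. In 12 of them the symbol had been turned into a date and in 53 it was a bare number. These rows held 0.025% of the FPKM in WT normoxia and 0.020% in WT hypoxia and were left out. The values had been rounded and came without gene lengths, so the depth of the WT libraries is unknown. The shRNA table gave gene lengths, and each FPKM value times its gene length was a whole multiple of 1 read, within 0.01 read, for 100.0% of values in both libraries. This gave 17859370 reads for shScr and 16780154 for shALKBH5. The deposited FPKM divided by 83.2% of that total in shScr and by 94.5% in shALKBH5. What the divisors count is not given in the sources used here. In the shRNA table, 1566 rows repeated a symbol, and the row with the highest mean FPKM was kept.

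Changes were computed as log2(FPKM + 1) in WT hypoxia minus WT normoxia, and in shALKBH5 minus shScr. This scale understates the change of genes with low values. Genes needed a mean FPKM of at least 1 over the 2 libraries compared. With 1 library per group no difference has a replicate check, so no p-value is given, and genes are counted by a fixed size rule of at least 2-fold in either direction. For genes of the shRNA table, a 95% exact (Clopper-Pearson) binomial interval of the read ratio is given on the log2 scale. It compares those 2 libraries, not the conditions, and covers counting error only. A gene with 0 reads in 1 library was given a lower bound against 3 reads.

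There were 43 gene lists, and a list needed 3 members past the filter. Each list's median log2 change was placed among 10000 random lists of the same size drawn from 10 bins of mean expression. A list is described as standing apart when its median lay at or outside the 2.5th and 97.5th percentiles. The named genes were the 8 highest and the 8 lowest changes among genes with a mean FPKM of at least 5, up to 4 members of each list with the largest changes, the 10 genes with the largest fall with shALKBH5 among those at least 2-fold higher in hypoxia, and 20 genes fixed by name. Genes under the filter are given by FPKM. The lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Genes named in the text outside this rule were chosen after their values were seen, and that is stated beside them.

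The alternatives were a pseudocount of 0.1 FPKM, no filter, a filter of 5 FPKM, centring on the median gene, rescaling to TPM, summing rows that share a symbol, and thresholds of 1.5-fold and 3-fold. After seeing the data, 3 more were added for the shRNA table, namely scaling to the total recovered reads, protein-coding genes only, and a minimum of 50 recovered reads.

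The size rule and the percentile were tested on simulated data. For the shRNA table, Poisson reads were drawn around the real means, with 50 genes changed at each of 4 sizes, and 11083 genes passed the filter. The rule called 0 of 50 genes changed 1.5-fold, 40 of 50 changed 3-fold, 48 of 50 changed 4-fold and 50 of 50 changed 8-fold, and 33 of 10883 unchanged genes. Besides the set changes, the simulated libraries differed by counting error only and shared the same divisor. These numbers thus leave out differences between cultures and between the divisors. For the WT table, where the depth is unknown, known changes were put into the values without noise, which checked only the arithmetic, since the rule then fixes the outcome. Of 60 random lists without a change, 2 lay outside the central range. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.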

Results

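Gene expression was measured by RNA-seq in U87 glioblastoma cells under 4 conditions with 1 library each, to find genes that depend on ALKBH5 in hypoxia. ALKBH5 is an enzyme that removes the m6A methyl mark from RNA. The shScr library held 17859370 recovered reads and the shALKBH5 library 16780154. The depth of the WT libraries is unknown. None of the differences below has a replicate check.

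ALKBH5 itself (ENSG00000091542, GRCh38 chromosome 17, 18183078 to 18209954) stood at 39.6 FPKM in WT normoxia and 83.5 FPKM in WT hypoxia, a log2 change of 1.06. In the shRNA table it stood at 186 FPKM with shScr and 113 FPKM with shALKBH5, from 8814 and 5711 reads. The log2 change of -0.71 was below the 2-fold rule, with a counting interval of the read ratio from -0.77 to -0.67. The ALKBH5 transcript was thus lower in the library labelled as its knockdown, at 0.608 of the shScr FPKM. The highest of 10 bins of mean FPKM, which holds ALKBH5, had a median change of -0.34 in this comparison. Part of the ALKBH5 fall was thus shared by genes of like abundance. Rescaled to TPM, the ALKBH5 change in hypoxia was 0.96, under the 2-fold rule. The ALKBH5 change with shALKBH5 was -0.46 under TPM and -0.53 when scaled to the total recovered reads. Set across the 2 separately normalised tables, shALKBH5 at 113 FPKM stood above WT hypoxia at 83.5 FPKM. Of the other m6A enzymes, the demethylase FTO had log2 changes of -0.47 in hypoxia and -0.27 with shALKBH5. The methyltransferase genes METTL3 and METTL14 had changes of -0.95 and -0.48 in hypoxia, and -0.30 and 0.48 with shALKBH5. Centred on the median gene, the changes in hypoxia were -0.12 for FTO, -0.60 for METTL3 and -0.13 for METTL14, and under TPM METTL3 was at -1.07, past the 2-fold rule. With shALKBH5 under TPM, FTO was at -0.08, METTL3 at -0.13 and METTL14 at 0.88.

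**Figure D1:**
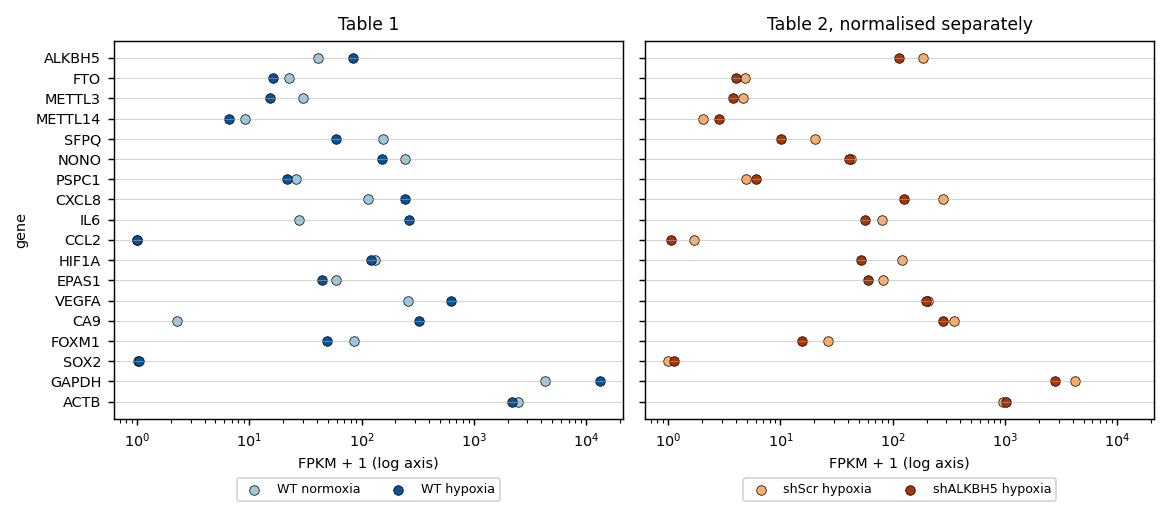
FPKM + 1 on a log axis for the genes fixed by name that both tables hold, with 1 point per library and no error bars since each group has 1 library. The left panel shows WT normoxia and WT hypoxia and the right panel shScr and shALKBH5 in hypoxia. The 2 panels were normalised separately. ALKBH5 stood at 39.6 and 83.5 FPKM on the left and at 186 and 113 FPKM on the right.

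The first comparison asked which genes differ between hypoxia and normoxia in WT cells. Genes that respond to the hypoxia-inducible factors were far higher in hypoxia. CA9, a carbonic anhydrase, went from 1.27 to 321.7 FPKM, a log2 change of 7.15. NDRG1, a stress-response gene, had a change of 6.24, HILPDA, a lipid droplet protein gene, 6.14, and IGFBP3, which encodes an IGF-binding protein, 6.66. Most ribosome biogenesis and heat shock genes were lower.

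Of 11050 genes past the filter, 819 were at least 2-fold higher in hypoxia and 1628 at least 2-fold lower. The median gene had a log2 change of -0.35, and the split depended on this shift. Centred on the median gene, 1317 were higher and 633 lower, so the share of higher genes among those counted was 33.5% as deposited and 67.5% when centred. The 8 highest genes were DEPP1 (8.01), CA9, IGFBP3, NDRG1, HILPDA, MT3 (5.89), TREM1 (5.81) and ANGPTL4 (5.59). MT3 encodes a metallothionein, TREM1 a receptor of myeloid cells and ANGPTL4 a secreted inhibitor of lipoprotein lipase. The 8 lowest were SERPINB2 (-3.73), a plasminogen activator inhibitor gene, RRS1 (-3.30), ODC1 (-3.24), the first enzyme of polyamine synthesis, GPATCH4 (-2.90), RRP9 (-2.83), HSPH1 (-2.83), P2RY8 (-2.80) and TNFRSF21 (-2.80).

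Of 37 lists with enough members, 10 stood above and 8 below the random lists. Random draws of genes give 1.85 outside on either side. Genes of a list can move together between 2 single cultures and some lists share members, so this number is only a rough guide. The HIF-responsive list had a median of 3.53, against -0.16 in random lists, with 38 of 39 measured members at least 2-fold higher. Glycolysis had a median of 1.63, with 14 of 17 higher. They included the lactate exporter gene SLC16A3 (4.85), and ALDOC (4.52), ENO2 (3.71) and PGK1 (3.13), which encode glycolytic enzymes. Collagens had a median of 2.08, with 9 of 11 higher, among them COL5A1 (3.70), COL1A2 (2.62) and COL6A1 (2.40). Matrix glycoproteins and proteases had a median of 0.46, with 7 of 25 higher and 4 lower, or 11 and 3 when centred. TGFBI (3.19), FN1 (2.67) and TIMP3 (2.66) were higher, and the urokinase gene PLAU (-2.20) was lower.

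JmjC and TET dioxygenases, oxygen-using enzymes that act on histones and DNA, had a median of 0.77, with 6 of 19 higher, or 10 when centred, among them KDM3A (1.47), KDM2B (1.30) and KDM5B (1.27), which encode histone demethylases. ATF4 and amino acid response genes had a median of 0.55, with 7 of 23 higher, or 10 when centred, including NUPR1 (2.09). Fibroblast and pericyte markers had a median of 1.53 over 4 measured members, with PDGFRB at 2.78 and COL1A1 at 2.16. Integrins (median 0.50, ITGA5 1.96), angiogenic factors (median 0.26) and endothelial markers (median 1.05 over 3 members, with PECAM1 at 1.05 and KDR at -2.34) also stood above. The angiogenic factors went both ways. Of 15 measured, 3 were at least 2-fold higher, including PGF (3.66), and 5 lower, including EREG (-2.18), or 3 and 4 when centred. The calls of these 3 lists ended under another filter or under TPM. Integrins lost theirs without a filter and at 5 FPKM, angiogenic factors under TPM, and endothelial markers without a filter.

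Ribosome biogenesis had a median of -1.79, with 22 of 25 members at least 2-fold lower, including RRS1, RRP9, RRP12 (-2.62) and NOP16 (-2.52). Heat shock genes had a median of -1.31, with 1 of 16 higher and 10 lower, the latter including the chaperone genes HSPD1 (-2.51) and HSPA1B (-2.28). G1/S and DNA replication genes had a median of -1.05, with 18 of 32 lower, including CCNE1 (-1.84) and MCM10 (-1.72). G2/M genes had a median of -0.77, with 8 of 30 lower, including CDC20 (-1.57). Homologous recombination and Fanconi anaemia genes had a median of -0.80 with 6 of 15 lower, and the TCA cycle genes -0.65 with 4 of 20 lower, among them IDH3A (-2.12). Centred on the median gene, the members at least 2-fold lower were 20 in ribosome biogenesis, 8 in heat shock, 6 in G1/S and DNA replication, 2 in G2/M, 1 in homologous recombination and 2 in the TCA cycle. Those at least 2-fold higher when centred were 2 in heat shock and 1 in the TCA cycle.

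Paraspeckle components, proteins of a nuclear body built on the RNA NEAT1, had a median of -0.69, with 4 of 16 lower, or 3 when centred. SFPQ had a change of -1.39 and NONO of -0.71. The chemokine and cytokine list had a median of -0.58 at percentile 2.08, and its members went both ways. Of 18 measured, 5 were higher, including IL6 (3.26), CCL20 (2.57) and CXCL8 (1.08), and 8 were lower, or 4 when centred, including CXCL1 (-2.41) and IL24 (-2.39). Its call ended without a filter and under TPM, and CXCL8 was at 0.98 under TPM. The other 19 lists lay within the random range, with medians from -0.67 to 0.57. Some of them left it under an alternative. Among these were metallothioneins (percentile 98.08 without a filter), cholesterol synthesis (99.81 at 5 FPKM) and replication-dependent histones (0.18 under TPM). HIF1A and EPAS1, which encode the oxygen-regulated subunits, had changes of -0.10 and -0.40, VEGFA 1.27, FOXM1 -0.80, GAPDH 1.63 and ACTB -0.17. Relative to the median gene, HIF1A was at 0.25 and ACTB at 0.18, so the direction of both turned. CCL2 was listed at 0 FPKM in both libraries, and the stem cell factor SOX2 at 0.02 and 0.04 FPKM.

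**Figure D2:**
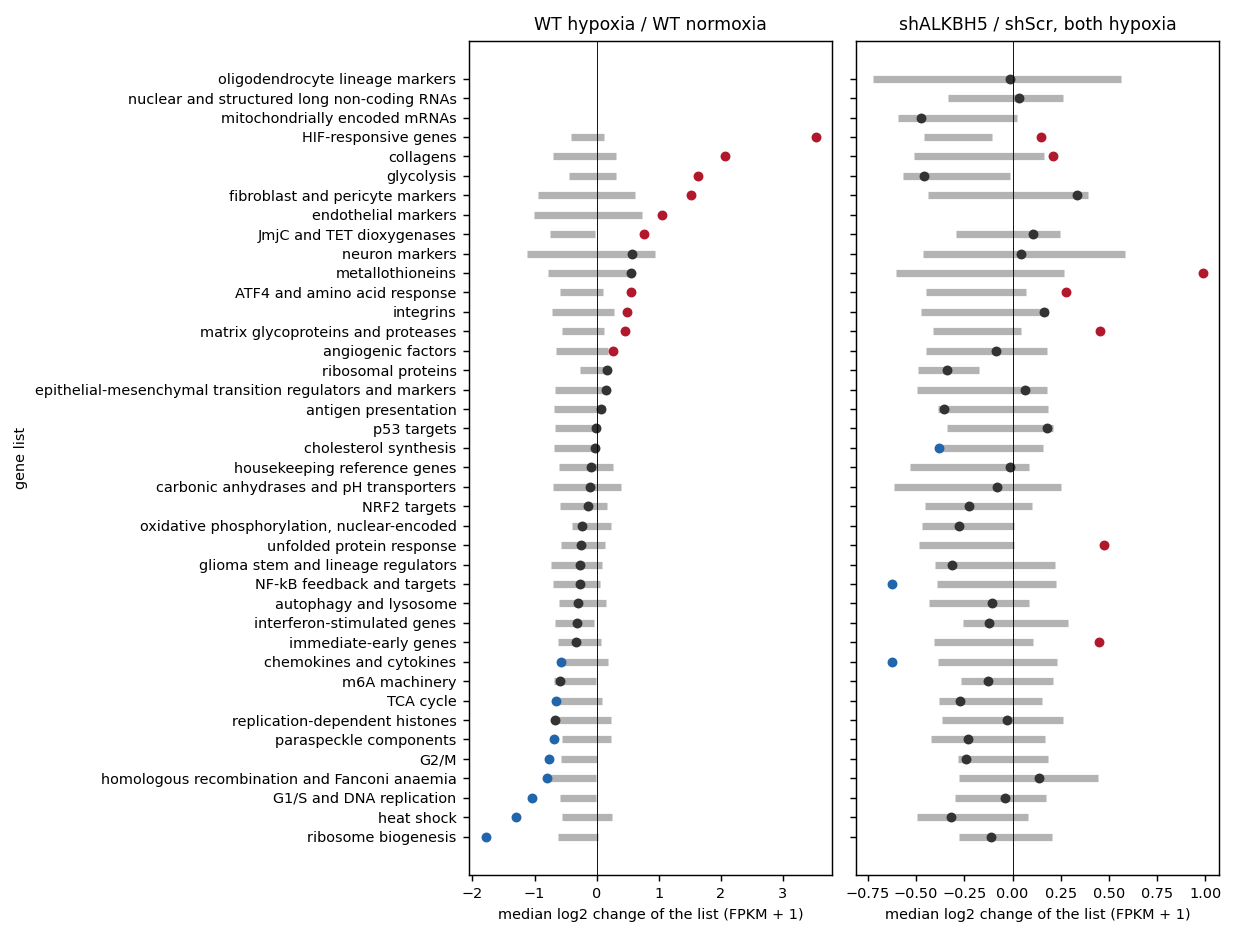
Each point is the median log2 change of a gene list (FPKM + 1), for WT hypoxia over WT normoxia on the left and shALKBH5 over shScr in hypoxia on the right, on different axis ranges. Grey bars span the central 95% of 10000 random lists matched on expression, with red points above that range, blue points below it and black points within it. The HIF-responsive list lay at 3.53 on the left and 0.15 on the right.

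The second comparison asked which genes differ with ALKBH5 knockdown in hypoxia. CXCL8, which encodes the neutrophil chemokine interleukin 8 (ENSG00000169429, GRCh38 chromosome 4, 73740506 to 73743716), stood at 281 FPKM with shScr and 124 FPKM with shALKBH5. Its log2 change was -1.17, with a counting interval from -1.23 to -1.12. Other inflammatory genes were lower in the same library, including IER3 (-1.73), an early-response gene, and NFKBIA (-1.22), the inhibitor of NF-kB. The HIF1A transcript was also lower, at -1.23 (counting interval -1.30 to -1.19), and at -0.98 under TPM, below the 2-fold rule. Of the 6 measured metallothionein genes, which bind metal ions, 3 were at least 2-fold higher.

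Of 10925 genes past the filter, 192 were at least 2-fold higher with shALKBH5 and 328 lower. The split turned with the scale. Scaling to the total recovered reads raised the shALKBH5 level relative to shScr by 0.18 on the log2 scale and gave 286 higher and 181 lower. TPM raised it by 0.26 and gave 1206 higher and 413 lower. Changes of scarce genes moved by other amounts, since a constant was added before the logarithm. The shift alone gave 409 higher and 159 lower, and the rest came from the smaller pseudocount and filter, since 1 TPM was 0.320 FPKM on average over the 2 libraries. The share of higher genes was 36.9% as deposited, 61.2% with total reads and 74.5% with TPM. CXCL8 was at -0.91 under TPM and -0.99 with total reads, below the 2-fold rule. NFKBIA was at -0.97 under TPM. Under TPM and with total reads, in that order, IL11 was at -0.90 and -0.96, and ALDOC at -0.78 and -0.85. The counting interval lay on the called side of 0, or the gene had 0 reads in 1 library, for 501 of the 520 genes counted.

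The 8 lowest genes were CRYAB (-3.10), a small heat shock protein gene, ID3 (-2.83), an inhibitor of differentiation, ATOH8 (-2.80), a transcription factor gene, SLC6A9 (-2.64), a glycine transporter gene, AGFG2 (-2.54), BDKRB1 (-2.52), the bradykinin B1 receptor gene, AKR1C1 (-2.49), an aldo-keto reductase gene, and GTF3C6 (-2.35). CRYAB went from 43.5 to 4.20 FPKM (1961 and 202 reads). The counting interval of its read ratio, to which no constant was added, was -3.59 to -3.16. The highest was RNU6-1, a U6 small nuclear RNA gene with many near-identical copies, with 0 reads in shScr and 44 in shALKBH5, at least 13.8-fold higher against 3 reads. The pseudogene SPCS2P4 (3.21) followed, and reads of both are uncertain because of their copies. The others were MCL1 (1.82), which encodes an anti-apoptotic protein, MT1M (1.81), LXN (1.76), MT1E (1.68), and the unnamed AC245100.3 (1.67) and AC079949.1 (1.67). Of the genes counted, 112 of 192 higher and 247 of 328 lower were protein-coding.

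Of 39 lists, 3 stood below and 7 above the random lists. Random draws of genes give 1.95 outside, with the same limit as in hypoxia. Chemokines and cytokines had a median of -0.62 at percentile 0.01, against -0.07 in random lists. Of 15 measured, 5 were at least 2-fold lower and none of the 15 higher, with CSF1 at -1.89, TGFB3 at -1.64, CXCL8 at -1.17 and IL11 at -1.14. IL6 had a change of -0.50. NF-kB feedback and targets had a median of -0.62 at percentile 0.02, with 4 of 14 lower, namely IER3, SOD2 (-1.36), IRAK2 (-1.25) and NFKBIA. The source of reads is uncertain for named genes that overlap another expressed gene. These were SOD2 (with WTAP), TGFB3 (IFT43), METTL3 (TOX4), DNAJB9 (PNPLA8 and THAP5), SLC6A9 (CCDC24), LXN (GFM1), TSC22D4 (C7orf61), PLPP1 (MTREX), FOXM1 (RHNO1) and BDKRB1 (AL355102.4). Cholesterol synthesis had a median of -0.38 at percentile 1.99, with SQLE (-1.67), a sterol synthesis enzyme gene, lower. That call ended without a filter and under TPM.

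The unfolded protein response list had a median of 0.47, against -0.27 in random lists, with 18 of 22 members above 0 and DNAJB9 (1.31) past the 2-fold rule. ATF4 and amino acid response genes had a median of 0.28, with 4 of 23 higher, namely MTHFD2 (1.30), SESN2 (1.29), GDF15 (1.20) and SLC7A11 (1.11). All 6 metallothioneins were above 0, with a median of 0.99, and 3 were higher, including MT1X (1.07). They are close paralogs that can share reads. Immediate-early genes had a median of 0.45, with 3 of 22 higher, or 5 when centred, including the phosphatase genes DUSP6 (1.47) and DUSP4 (1.29). EGR1 (-1.31) was lower. Matrix glycoproteins and proteases had a median of 0.45, with 3 of 28 higher, namely MMP1 (1.46), LUM (1.34) and SPARC (1.08), and CYR61 (-1.41) lower. Collagens had a median of 0.21 with no member of the 13 past the rule.

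The HIF-responsive list stood above the random lists with a median of 0.15, against -0.30. Of its 40 members 1 passed the rule, SLC2A3 (1.02), a glucose transporter gene. CA9 was at -0.32 and HILPDA at -0.99. VEGFA was at -0.06, and at 0.20 under TPM and 0.13 with total reads, so its direction turned with the scale. The other 29 lists lay within the random range, with medians from -0.47 to 0.33. NEAT1 went from 2.08 to 5.19 FPKM (log2 change 1.01), and MALAT1, another nuclear RNA, had a change of 0.27. SFPQ was at -1.01 (counting interval -1.20 to -0.98), and under the 2-fold rule when centred, in TPM and with total reads. PSPC1 was at 0.29. NONO was at -0.05, and at 0.20 under TPM and 0.12 with total reads, so its direction turned. EPAS1 was at -0.44, FOXM1 at -0.78, GAPDH at -0.58 and ACTB at 0.12. CCL2 was at 0.711 and 0.0635 FPKM (21 and 2 reads), and SOX2 at 0 and 0.126 FPKM (0 and 5 reads).

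The third comparison asked which genes higher in hypoxia were lower with shALKBH5. Among 9262 genes past the filter in both tables, 746 were at least 2-fold higher in hypoxia, and 28 of these were at least 2-fold lower with shALKBH5. Independent lists of these sizes would share 17.8, and random genes of the same abundance gave a median of 23 (central 95% 15 to 32). CXCL8 was among the 28, though under TPM it was below 2-fold in both comparisons. ALDOC was among them too, and so were the 10 with the largest fall with shALKBH5. These were CRYAB, SLC6A9, BDKRB1, WISP1 (-1.86), PPP1R3C (-1.78), TMEM119 (-1.72), TSC22D4 (-1.59), PLPP1 (-1.53), MRPS6 (-1.42) and TWIST1 (-1.41). PPP1R3C, a glycogen-targeting phosphatase subunit gene, had a log2 change of 3.64 in hypoxia, and TWIST1, a mesenchymal transcription factor gene, 2.31. CRYAB (1.00) and SLC6A9 (1.01) lay at the edge of the rule in hypoxia. Set across the 2 separately normalised tables, CRYAB stood at 4.79 FPKM in WT hypoxia, 43.5 with shScr and 4.20 with shALKBH5. PLPP1 stood at 21.4, 63.3 and 21.2 FPKM in that order. Of the 10, only BDKRB1 and MRPS6 were lower with shScr than in WT hypoxia. The 10 were chosen for their fall from shScr to shALKBH5, which favours genes with high shScr levels. The median gene had a log2 difference of -0.73 with shScr over WT hypoxia, so these levels say little about single genes. The series holds no shScr library in normoxia, so induction of these genes in the shRNA cells was not measured. MRPS6 overlaps SLC5A3 on the same strand and both were among the 28, so 1 locus with reads of uncertain source counted 2 times.

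A further 29 of the 746 were at least 2-fold higher with shALKBH5, where independent lists would share 8.46 and random genes of the same abundance gave 9 (4 to 15). They included LXN and SLC2A3. The median knockdown change was -0.08 in the 746 genes higher in hypoxia, 0.02 in the 1213 genes lower in hypoxia and -0.04 in the 7303 others. Random genes matched to the 746 on abundance had a median of -0.16 (central 95% -0.20 to -0.11), so the 746 lay above them, at percentile 99.96. With a filter of 5 FPKM, the 28 became 17 and the ratio to independent lists 0.99.

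**Figure D3:**
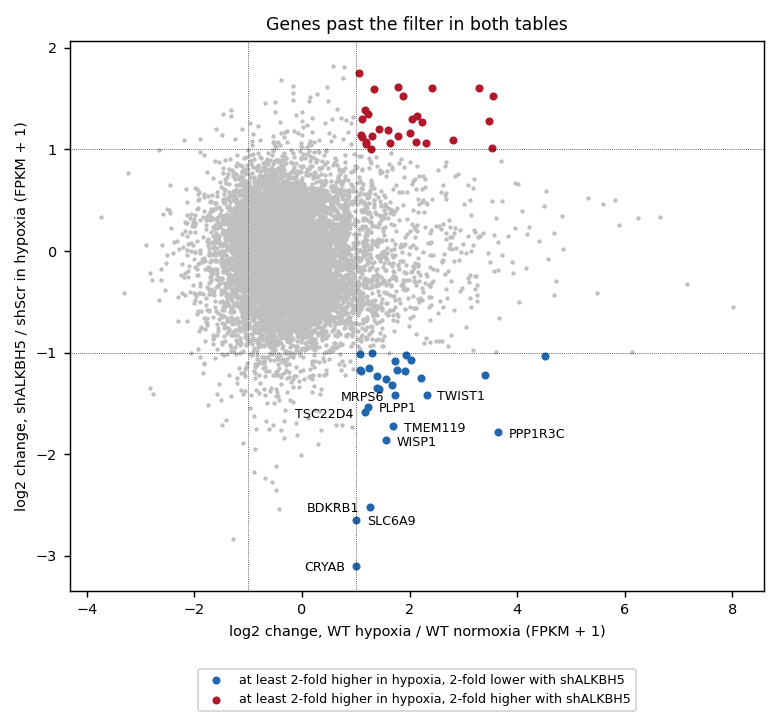
Each point is a gene past the filter in both tables, with its log2 change in WT hypoxia over WT normoxia on the x axis and in shALKBH5 over shScr on the y axis (FPKM + 1), and dotted lines at 2-fold. Blue points are the 28 genes higher in hypoxia and lower with shALKBH5, with the 10 lowest named, and red points the 29 higher in both.

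The 2 hypoxic control libraries, WT and shScr, come from tables normalised separately, so their levels were only set side by side. Over 10510 genes past the filter, the log2 difference centred on its median had an SD of 1.22, and 3511 genes differed by at least 2-fold. In the 9262 genes above, the SD was 1.09 between these controls, 0.88 between hypoxia and normoxia, and 0.48 between shALKBH5 and shScr. The controls also differ by transduction and possibly by batch, and their tables by the genes they hold (18964 and 58735 rows). Differences between the tables can enter the 1.09 but not the 2 SDs within a table. The 1.09 is thus an upper guide to replicate error, not an estimate of it. IL1B, chosen after its values were seen, stood at 1048 FPKM in WT hypoxia and 21.6 FPKM with shScr.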

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

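The alternatives that used total recovered reads, protein-coding genes only and at least 50 recovered reads were chosen after seeing the data. No paired analysis was possible because each group has 1 library. No single gene or list past its threshold changed sign. The balance of higher and lower counts turned with centring and at 3-fold in hypoxia, and with TPM and total reads with shALKBH5. VEGFA and NONO with shALKBH5, and HIF1A, PSPC1 and ACTB in hypoxia, all below the 2-fold rule, changed sign with the scale. The counts depended on the size threshold and the pseudocount. At 1.5-fold, 1461 genes were higher and 3906 lower in hypoxia, 928 higher and 1489 lower with shALKBH5, and the overlaps of genes higher in hypoxia were 189 lower and 155 higher with shALKBH5. At 3-fold these were 370, 340, 50, 66, 2 and 3. A pseudocount of 0.1 FPKM gave 440 higher and 531 lower with shALKBH5 and overlaps of 44 lower and 47 higher. A filter of 5 FPKM gave 82 higher, 218 lower, overlaps of 17 and 16, and a ratio to independent lists of 0.99 for the genes lower with shALKBH5. Centring gave 1317 higher and 633 lower in hypoxia. TPM gave 1206 genes higher with shALKBH5, an overlap of 83 higher in both, and ALKBH5 at 0.96 in hypoxia. Total reads gave 181 lower with shALKBH5 and overlaps of 18 lower and 44 higher. Protein-coding genes alone gave 112 higher with shALKBH5, and at least 50 reads gave 123. The counts at other thresholds follow from the threshold, the smaller counts under stricter filters from testing fewer genes, and those under centring and total reads from the shift they apply. The larger counts with a pseudocount of 0.1 FPKM follow from the smaller constant, which enlarges log2 changes, most for scarce genes. For the ratio the cause was not tested. Summing rows that share a symbol altered 11 genes past the filter and no count. ALKBH5 with shALKBH5 ranged from -0.72 to -0.46.

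For single genes and lists the threshold was the 2-fold rule and the central random range. Of the list medians under an alternative other than centring, which moves random lists alike, and summing, 309 kept their side, 20 passed it and 8 no longer did. For rare transcripts the counts rest on few reads, as 133 of the 520 genes counted with shALKBH5 had a mean under 50 reads.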

Other observations

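The test of gene length for the chemokine and NF-kB lists and that of BMP-SMAD targets were written before their results were seen, and the other tests were chosen after. The genes named here were chosen after their values were seen unless the fixed rule names them. Mitotic genes had a median of -0.24 with shALKBH5 at percentile 4.93, inside the random range. The list lay below that range with a pseudocount of 0.1 FPKM (median -0.35) and with a filter of 5 FPKM (median -0.58, percentile 0.05). It stayed inside without a filter, under TPM and with total reads (percentiles 6.69, 4.535 and 2.87). Of its 27 measured members, 4 were at least 2-fold lower, namely CDC20 (-1.41), BIRC5 (-1.40), CDC25B (-1.38) and PLK1 (-1.30). Other lists also left the range under some settings. Antigen presentation lay below it with a pseudocount of 0.1 FPKM, under TPM and with total reads (percentiles 1.86, 2.05 and 1.885). Glioma stem and lineage regulators lay below it with a filter of 5 FPKM (0.14). Above it lay p53 targets without a filter (98.5) and under TPM (97.585), integrins with total reads (97.54) and housekeeping genes with a filter of 5 FPKM (97.57). Among the 29 genes higher in both comparisons were GJB2, a gap junction gene (3.56 in hypoxia, 1.53 with shALKBH5), TNFSF13B, which encodes the B cell factor BAFF (3.28 and 1.60), and SESN2, a stress-response gene (1.11 and 1.29). Of small RNA genes past the 2-fold rule with shALKBH5, 20 of microRNA type were higher and 10 lower, 2 of snoRNA type were higher and 8 lower, and 8 of snRNA type were higher and 3 lower. Of mitochondrial tRNA genes 5 were lower and 0 higher, and of those typed as miscellaneous RNA 2 were lower and 0 higher. Reads of nuclear small RNA genes can come from the host transcripts they lie in. Short genes also pass the filter on few reads. Of the 192 genes of all types counted as higher, 47 had a mean under 20 reads. Whether these counts by type exceed counting error was not tested.

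Abundant genes were lower than scarce genes in the shALKBH5 library. The median log2 change went from 0.12 in the lowest of 10 bins of mean FPKM to -0.34 in the highest, which holds ALKBH5, CXCL8 and GAPDH. Within each of 5 bins of gene length, the difference between the highest and the lowest of 5 abundance bins stayed below 0, and the weakest was -0.33 (95% bootstrap interval over genes -0.46 to -0.20), which argues against gene length as the whole cause. With a pseudocount of 0.1 FPKM the difference was -0.50 (-0.54 to -0.47), which argues against shrinkage by the pseudocount. An even background could raise scarce genes, but sense-intronic genes gained 0.0296 FPKM (at most 0.0440), and genes in the 5th bin would need 1.38 FPKM, which argues against it. The knockdown itself and a difference between the 2 cultures were not tested, since each group has 1 library.

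Genes higher in hypoxia were in excess among genes lower with shALKBH5, 28 against 17.8 for independent lists. Random genes of the same abundance gave a median of 23 (central 95% 15 to 32), with the observed number at percentile 84.7, so abundance may account for this excess. The same genes were also in excess among genes higher with shALKBH5, 29 against 9 (4 to 15), at percentile 100. Each number was divided by the mean of its random sets, 23.4 for lower and 8.97 for higher, and the ratio of lower to higher was 0.371 (exact binomial interval over genes 0.213 to 0.646). The ratio stayed below 1, upper bound included, which was the outcome set against a one-way dependence of the induced genes as a set. That interval, however, counts genes as independent, and genes can move together between 2 single cultures. A one-way dependence of the induced genes on ALKBH5, as a set or for single genes such as CXCL8, therefore stays open, since each group has 1 library.

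The chemokine and NF-kB lists shared 0 members and both were lower with shALKBH5. Matched on abundance and gene length, the percentiles were 0.06 and 0.03, and 0.06 argues against short genes. Whether the lower medians follow from the knockdown or from a difference between the 2 cultures was not tested, since each group has 1 library.

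As ID3 and ATOH8, targets of BMP-SMAD signalling, were among the lowest genes with shALKBH5, lower BMP-SMAD target expression was tested on other targets. Over 12 measured genes the median was -0.33 at percentile 4.60, between the bounds set, so the test left this open. Of the 12, 4 were above 0. BAMBI (-1.49) was the 1 member at least 2-fold lower, and HES1 (1.07) the 1 at least 2-fold higher.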
